A study of Mus musculus with 6 samples.

How the data were processed

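Tissue from the posterior nasal septum, mucosa and bone together, was taken from mice on a control or a zinc-deficient diet, per the labels. Total RNA, 500 ng per library, was depleted of ribosomal RNA with a depletion kit of version 2 and made into Illumina libraries with the NEBNext Ultra II RNA kit, per the labels. Ribosomal depletion without poly(A) selection keeps RNAs that lack a poly(A) tail, such as most histone mRNAs and small nuclear and nucleolar RNAs, and leaves a remainder of ribosomal RNA. The labels do not say that the kit marks the strand, so reads of a gene and of an antisense partner cannot be told apart.

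The authors deposited one table of 41709 genes with whole-number counts per gene for each of the 6 libraries, named total counts per the file headers. The aligner, the counting tool, the genome build and the gene annotation are not given in the sources used here. The same table held RPKM values and values named CPM per the file headers. In the deposited CPM columns, the count was divided by 1 constant per library that differed from the column total, so these columns summed to between 924909 and 1098881. Within each library the deposited RPKM was the count times a constant per gene. The deposited table and 4 shorter lists also held the authors' own comparison of the diets, as a fold change, a log2 fold change, a p-value and an FDR-adjusted p-value. The test behind the authors' comparison is not given in the sources used here.

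Gene coordinates are printed as the deposited table gives them, counted from 1, and their build is not given in the sources used here. Of 38619 identifiers that matched GENCODE M21 on GRCm38, 2.45% had the same start and end and 98.68% the same span, so the reference was used only for biotypes by gene identifier. Of 261 gene names of the immunoglobulin segment pattern, 258 had 0 counts in each library, and the only one tested, Ighmbp2, is not a segment (log2 fold change 0.22). Immunoglobulin segments were therefore not analysed here.

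The counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersions, TMM scaling, the low-count filter filterByExpr and the diet as the only term. Tests were two-sided and adjusted by Benjamini-Hochberg at 0.05. CPM values printed are counts scaled by the TMM-scaled library size, apart from the summed odorant receptor CPM and the floor of 3 counts. Those 2 used the column total without TMM, and shares in percent are of the column total. The standard error printed for a gene was derived from its test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The floor of 3 counts covers counting error only, since the reads carry no molecular identifiers, and the 95% interval printed for a fitted term covers the spread between libraries. No 2 libraries of a diet agreed within sampling noise, so 3 libraries per diet were counted. A set of 66 gene lists (cell types of the nose, bone, marrow and blood, and pathways) was fixed before the data were examined. The 63 with at least 5 tested members, apart from a list of sex-linked genes, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera compares a list with all other genes, and with many members that share cell types a preset correlation can be too low, so each list was also tested with a correlation estimated per list and with fry, which asks whether a list's genes move one way. The summed odorant receptor CPM was compared by an exact permutation test, which cannot go below 0.1 with 3 against 3.

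The genes named were chosen by a rule set before the data were examined. It took up to 10 rises and 10 falls past the test with separate CPM ranges and a mean of at least 1 CPM in the higher diet, leaving out unnamed gene models, pseudogenes, receptors and immunoglobulin segments. It added up to 4 passing members per list, a fixed set of genes of zinc handling, epithelial cell types, bone and marrow whatever their test, and the 2 most abundant members of a list discussed that had no passing member. This gave 10 rises and 5 falls. One gene of the fixed set is not reported here. Ces1a, Gm23262, H3c10, H1f3, H3c6, H4c2, H1f4, Nr4a2, Cdc20, Mcm5, Runx2, Col3a1, Tubb3, Nr1d1, Npas2, Obp1a, Mup4, Lcn11, Rn18s-rs5, Rnu2-10, mt-Nd3, mt-Atp8, Ddx3y, Uty and Xist were named after their values were seen.

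Alternatives set before the data were examined were the replicate number as a block, leaving out each library, median-of-ratios and upper-quartile scaling, no low-count filter or a stricter one of 100 counts, leaving out marrow and blood genes, DESeq2 1.42.0, limma-voom, a limma fit on log2(RPKM + 1) of genes with a mean RPKM of at least 1 in a diet, a fold of at least 2 and an adjusted p of 0.01. Alternatives added after seeing the data were the edgeR likelihood ratio test, a marrow score as a covariate and leaving out the 10 most abundant genes. The marrow score was the mean over the erythroid, neutrophil precursor and developing B cell lists of each library's mean log2 CPM.

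The procedure was tested on simulated counts of the comparison of the diets, with 18022 genes tested, drawn from the means and totals of the real libraries. The edgeR test recovered 5 of 50 genes changed 1.5-fold, 29 of 50 changed 2-fold, 40 of 50 changed 4-fold and 46 of 50 changed 8-fold, with 7 false calls, and it made 1 call where no gene was changed. DESeq2 made 18 false calls and recovered 33 of 50 genes changed 2-fold. The likelihood ratio test made 14 and recovered 32, and limma-voom made 4 and recovered 23. Of 20 simulated lists shifted 1.5-fold, camera recovered 20 with no false call, the estimated correlation 19 and fry 20 with 1 false call. The simulated genes were drawn independently, whereas members of some real lists moved together (estimated correlation 0.86 for erythroid genes and 0.30 for histones). False calls among lists with correlated members were therefore not tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.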

Results

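RNA was sequenced from the rear part of the nasal septum of mice kept on a control diet or on a zinc-deficient diet between 4 and 8 weeks of age. The dissected pieces held mucosa together with bone, so that olfactory epithelium, respiratory epithelium, glands, bone and marrow could all give RNA to one library. There were 3 libraries per diet, numbered 4, 5 and 6 in each. The series concerns the renewal of the olfactory epithelium, and its single comparison asks which genes differ in this tissue when the diet lacks zinc. The control libraries held 13059798, 11731999 and 16748740 counts in genes, and the zinc-deficient libraries held 14397826, 16163294 and 18727863. Between 22876 and 23896 of the 41709 listed genes had counts in a library. A floor of 3 counts corresponded to between 0.160 and 0.256 CPM (counts scaled to library size). Over the 1000 most variable genes, the first principal component held 35.75% of the variance, with control libraries at −13.65, −8.81 and −40.51 and zinc-deficient libraries at 27.27, 30.24 and 5.45. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries, which may in part be technical.

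Under the zinc-deficient diet, 14 of 58 tested genes for replication-dependent histones, the proteins that package newly copied DNA, rose. The other 44 did not pass over all genes, and the histone list, which passed camera with its preset correlation, had adjusted p = 0.597 with an estimated correlation. The genes that fell were Nr4a3, an immediate-early nuclear receptor gene, the chaperone genes Hsph1 and Hsp90aa1, both mitochondrial ribosomal RNAs and the small RNA gene Gm23262. Of 18427 genes tested with edgeR, 22 passed an adjusted p of 0.05, of which 16 rose and 6 fell. The 16 comprised 14 histone genes, Igll1, which encodes a part of the surrogate light chain of pre-B cells, and Ces1a, a carboxylesterase gene. Ces1a (chromosome 8, 93746842 to 93774820) rose from 81.5 ± 12.8 to 161 ± 12.7 CPM (SD, n = 3), a log2 fold change of 0.98 with a standard error of 0.14 (edgeR adjusted p = 0.0291). All 22 had CPM ranges that did not overlap between the diets, as had 3477 of the tested genes (18.87%, against 10% by chance). The count of 22 became 50 without control replicate 4, and 9 without control replicate 5, control replicate 6 or zinc-deficient replicate 5. Without control replicate 5 a single gene was higher, and it was a histone gene. DESeq2 called 349 genes, limma-voom 6 and a limma fit on log2(RPKM + 1) 14, all of the last being higher. That fit added no scaling between libraries and tested 12932 genes, whose median log2 fold change was 0.095, against −0.0021 over the genes tested with edgeR.

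The replication-dependent histone genes were the group with the largest number of calls. All 58 tested members had a positive log2 fold change, with a median of 1.33. Of these, 14 rose over all genes tested and 47 rose when adjusted over the list alone. DESeq2 called 37 of them, limma-voom 3, and edgeR 0 with a marrow score (the mean log2 CPM of 3 marrow lists) beside the diet. The count of 14 became 25 without control replicate 4, 1 without control replicate 5, 6 without control replicate 6 and 7 without zinc-deficient replicate 5. The list means were 3.8, 3.07 and 3.12 log2 CPM in control replicates 4, 5 and 6 and 4.93, 4.62 and 4.69 in the zinc-deficient ones, where marrow scores were 3.38, 2.10 and 1.06 against 3.86, 3.96 and 3.79, and the cell cycle lists were higher as well. H4c6 (ENSMUSG00000069274, chromosome 13, 23735432 to 23735822) rose from 12.8 ± 3.52 to 50.6 ± 6.31 CPM (SD, n = 3), a log2 fold change of 1.98 with a standard error of 0.20 (edgeR adjusted p = 0.00616). H2bc12 (chromosome 13, 22220040 to 22220515) rose from 5.68 ± 1.95 to 23.2 ± 0.716 CPM, with a log2 fold change of 2.03 and a standard error of 0.24 (edgeR adjusted p = 0.0118). H2bc7 rose by 2.87, H2ac13 by 2.5, H2ac22 by 2.37, H2ac10 by 2.35, H2ac11 by 2.01 and H4c1 by 1.64 on the log2 scale. These genes lay on chromosome 13 between 21900592 and 23945213, whereas H3c13 (chromosome 3, 96175970 to 96176457) rose by 1.57, from 34.8 ± 7.89 to 104 ± 33.3 CPM. H3c10, H1f3, H3c6, H4c2 and H1f4 also passed, with log2 fold changes from 0.85 (H1f4) to 1.56 (H3c10). Reads from near-identical histone genes can be split between copies in counting, so single members are uncertain. The summed CPM of the 58 genes, which does not depend on that split, was 1561 ± 200.3 under the control diet and 3080 ± 674 under the zinc-deficient diet, with separate ranges (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The list passed camera with its preset correlation (adjusted p = 4.08e-35) and had adjusted p = 0.597 with an estimated correlation. With the marrow score beside the diet it still passed camera with the preset correlation (adjusted p = 9.72e-18), with 56 of 58 members positive. The diet term of its mean then had a 95% interval from −0.01 to 1.82, which includes 0.

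**Figure D1:**
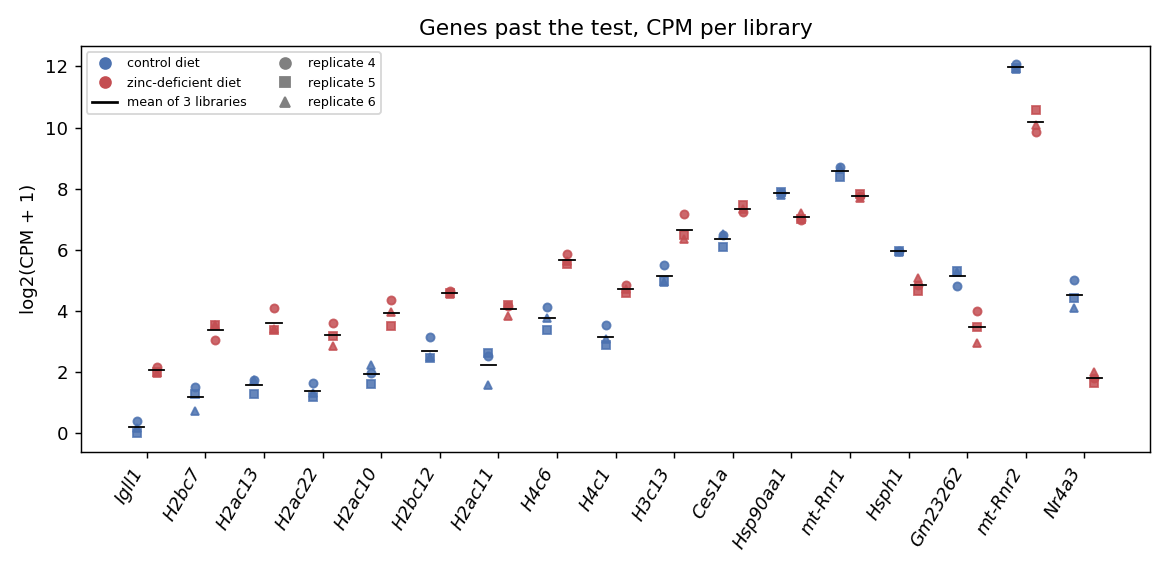
Expression of genes past the test, apart from the histone genes H3c10, H1f3, H3c6, H4c2 and H1f4, as log2(CPM + 1) on the vertical axis. Points are the 3 control (blue) and 3 zinc-deficient (red) libraries, with marker shapes for replicates 4, 5 and 6 and a line at the mean of the 3 libraries. The ranges of the diets are separate for each gene shown, with H4c6 at 12.8 against 50.6 CPM and Nr4a3 at 22.6 against 2.54 CPM.

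Nr4a3 (ENSMUSG00000028341, chromosome 4, 48045153 to 48086447) had the smallest adjusted p of all genes tested. It fell from 22.6 ± 7.84 to 2.54 ± 0.425 CPM (SD, n = 3), a log2 fold change of −3.14 with a standard error of 0.28 (edgeR adjusted p = 0.00295). The related receptor gene Nr4a2 had a log2 fold change of −1.56 and did not pass (edgeR adjusted p = 0.096). The list of 18 tested immediate-early genes, which are induced within minutes to hours of a stimulus, had a median of −0.36 with 1 member past the test. It was lower by camera (adjusted p = 0.0098), with adjusted p = 0.597 with an estimated correlation. Of 13 heat shock genes, 2 fell over all genes and 2 when adjusted over the list alone. Hsph1 (chromosome 5, 149537752 to 149559841), which encodes a co-chaperone of Hsp70, fell from 61.0 ± 1.05 to 28.2 ± 4.13 CPM, with a log2 fold change of −1.11 and a standard error of 0.14 (edgeR adjusted p = 0.0147). Hsp90aa1 (chromosome 12, 110657039 to 110669162), the stress-inducible cytosolic Hsp90 gene, fell from 230 ± 6.72 to 134 ± 12.2 CPM, with a log2 fold change of −0.78 and a standard error of 0.12 (edgeR adjusted p = 0.0399). The heat shock list had a median of −0.32 (camera adjusted p = 0.000454, and adjusted p = 0.597 with an estimated correlation).

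Both ribosomal RNAs of the mitochondrial genome fell. The large one, mt-Rnr2 (MT, 1094 to 2675), fell from 4015 ± 238 to 1173 ± 308 CPM (SD, n = 3), a log2 fold change of −1.77 with a standard error of 0.21 (edgeR adjusted p = 0.0118). The small one, mt-Rnr1 (MT, 70 to 1024), fell from 387 ± 45.9 to 217 ± 10.26 CPM, a log2 fold change of −0.84 with a standard error of 0.14 (edgeR adjusted p = 0.0479). Together they held 0.436% ± 0.0419 of all counts under the control diet and 0.142% ± 0.0408 under the zinc-deficient diet. None of the 13 mitochondrial mRNA genes passed over all genes, and 1 was lower when adjusted over the list alone. Of their most abundant members, mt-Co1 had a log2 fold change of −0.0095 and mt-Co2 −0.31. With an unadjusted p under 0.05 there were 2, and DESeq2 called 2. Their share of all counts was 0.718% ± 0.0770 and 0.662% ± 0.296. The 13 had a median of −0.25 and were lower by camera (adjusted p = 0.0229), with adjusted p = 0.811 with an estimated correlation, and without zinc-deficient replicate 4 the median was 0.055. With a marrow score beside the diet that list did not pass camera (adjusted p = 0.434). The libraries were made from total RNA after removal of ribosomal RNA, so the ribosomal values are what that step left. Gm23262 (chromosome 7, 110675267 to 110675434), annotated as a small nucleolar RNA, fell from 34.5 ± 6.16 to 10.6 ± 4.08 CPM, with a log2 fold change of −1.71 and a standard error of 0.26 (edgeR adjusted p = 0.0373).

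**Figure D2:**
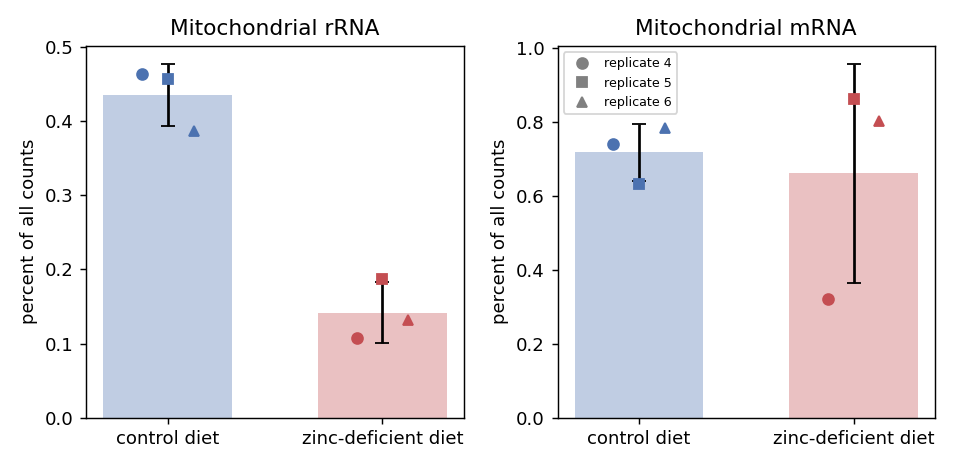
Share of all counts, in percent, taken by the 2 mitochondrial ribosomal RNAs (left) and by the 13 mitochondrial mRNA genes (right). Bars are means of 3 libraries, error bars are the SD and markers are libraries; ribosomal RNA was at 0.436% against 0.142%, and mRNA at 0.718% against 0.662%.

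Genes of the cell cycle were higher as lists under the zinc-deficient diet in camera with its preset correlation, with adjusted p = 0.597 with an estimated correlation for both lists and no member past the test over all genes. With a marrow score beside the diet neither list passed camera (adjusted p = 0.181 for G2 and M and 0.101 for S). All 25 genes of the G2 and M phases had a positive log2 fold change, with a median of 0.80, and 13 rose when adjusted over the list alone. Cdc20, which activates the anaphase-promoting complex, had a log2 fold change of 1.5 (edgeR adjusted p = 0.0673), and Mki67, a marker of cycling cells, had 1.01 with a standard error of 0.56 (edgeR adjusted p = 0.524). Top2a, a topoisomerase gene of dividing cells, had 0.56. Of 25 genes of S phase, 23 were positive, with a median of 0.51, and 6 rose when adjusted over the list alone, among them Mcm5, a subunit of the replicative helicase, at 1.26. The more abundant Mcm7, of the same helicase, had 0.40 and Pcna, the sliding clamp gene, 0.15. Over all genes edgeR passed none of either list, of which 13 and 10 had an unadjusted p under 0.05, and DESeq2 passed 6 of the first list and 4 of the other. Camera gave adjusted p = 1.52e-12 for the G2 and M list and 1.15e-08 for the S list.

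Of the marrow and blood lists, 6 were higher in camera with its preset correlation, as the histone and cell cycle lists were, and 5 did not pass. Each of the 6 had adjusted p = 0.597 with an estimated correlation. All 20 erythroid genes were positive with a median of 1.47, and Hba-a1, an alpha-globin gene, was at 144 ± 105.5 CPM under the control diet and 366 ± 224 under the zinc-deficient diet (SD, n = 3). The globin genes Hba-a2 and Hbb-bs had log2 fold changes of 1.29 and 1.32. Neutrophil precursor genes had a median of 1.78 over 12 members, with the neutrophil elastase gene Elane at 3.86 ± 3.44 and 14.9 ± 1.35 CPM. Of its most abundant members, Ngp, a granule protein gene, had 1.82, and Ltf, the lactoferrin gene that glands also express, had −1.01. Developing B cell genes had a median of 1.57 over 14 members, of which Igll1 (ENSMUSG00000075370, chromosome 16, 16678535 to 16681849) rose over all genes and 2 rose when adjusted over the list alone. Igll1 had 4, 0 and 2 counts in the control libraries and 48, 52 and 56 in the zinc-deficient ones, a log2 fold change of 4.34 with a standard error of 0.66 (edgeR adjusted p = 0.0373). Cd79a, of the B cell receptor, had 2.30 with a standard error of 1.20. Genes of mast cells, basophils and eosinophils had a median of 2.31 over 7 members, genes of mature neutrophils 0.99 over 13 and genes of megakaryocytes and platelets 0.63 over 13. Their most abundant members were Hdc at 0.06 and Prg2 at 2.31 in the first list, Mmp9 at 0.08 and Cd177 at −0.83 in the next, and Itgb3 at 0.28 and Itga2b at 0.63 in the last. Camera adjusted p was between 9.29e-10 (erythroid) and 0.00408 (mature neutrophil) for these 6 lists. The list means of control replicate 4 lay above the lowest zinc-deficient library for erythroid genes (4.07 against a lowest of 3.97 log2 CPM), mature neutrophils (3.37 against 3.18), developing B cells (2.58 against 2.35) and megakaryocytes and platelets (1.85 against 1.63), so these ranges overlapped. The lists that did not pass were mature B cells, with a median of 0.76 over 12 members, T and NK cells with 0.32 over 7, monocytes and macrophages with 0.03 over 17, plasma cells with −0.11 over 9 and dendritic cells with −0.25 over 13 (camera adjusted p = 0.243, 0.361, 0.629, 0.332 and 0.187). The marrow score, the mean log2 CPM of the erythroid, neutrophil precursor and developing B cell lists, was 3.38, 2.10 and 1.06 in control replicates 4, 5 and 6, and 3.86, 3.96 and 3.79 in the zinc-deficient replicates. With that score beside the diet, 2 genes passed in all, of which 1 was among the 22. The histone median was then 0.88, the G2 and M median 0.04 and the S median 0.24.

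**Figure D3:**
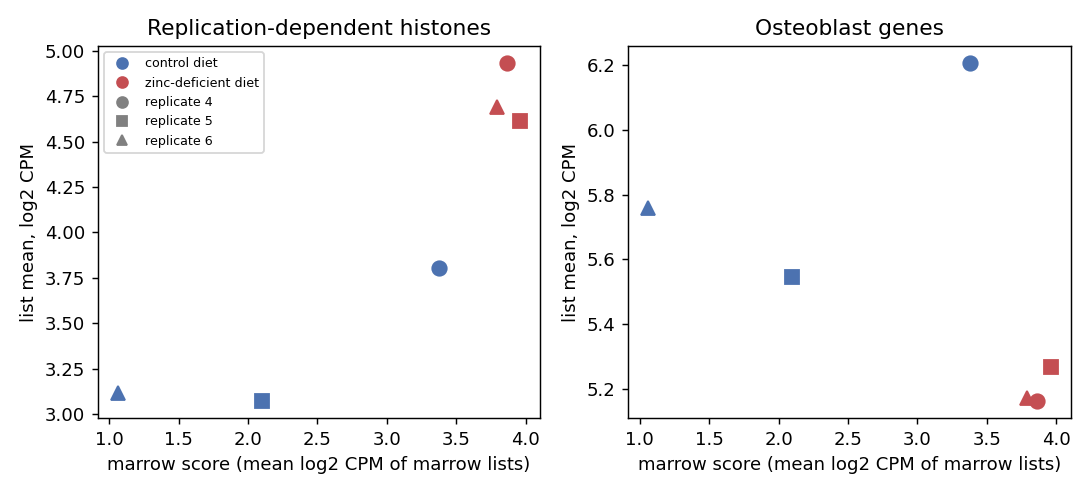
Mean log2 CPM of the replication-dependent histone genes (left) and of the osteoblast genes (right) against the marrow score, for 3 control (blue) and 3 zinc-deficient (red) libraries. The zinc-deficient libraries lie between 3.79 and 3.96 on the marrow score and the control libraries at 1.06, 2.10 and 3.38.

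Osteoblast and matrix genes were lower under the zinc-deficient diet as lists in camera with its preset correlation, with adjusted p = 0.597 with an estimated correlation for both and no member past the test over all genes. Osteoclast genes had a median of −0.08 over 12 members and chondrocyte genes −0.007 over 16, and neither list passed (camera adjusted p = 0.423 and 0.836). Of 19 osteoblast genes 18 were negative, with a median of −0.68, and 8 fell when adjusted over the list alone. Bglap, which encodes osteocalcin, was at 107 ± 36.9 and 49.9 ± 17.5 CPM (SD, n = 3), a log2 fold change of −1.10 (edgeR adjusted p = 0.254), and Runx2, a transcription factor gene of osteoblasts, had −0.57 (edgeR adjusted p = 0.212). Col1a1 and Col1a2, which encode the chains of type I collagen and were the most abundant members of both lists, had −0.86 and −0.80. The list of 18 collagen and matrix genes had a median of −0.58, and 12 fell when adjusted over the list alone, among them Col3a1, a fibrillar collagen gene, at −1.54 (edgeR adjusted p = 0.107). Of the osteoblast genes 10 had an unadjusted p under 0.05 and DESeq2 passed 4, and of the matrix genes 13 had and DESeq2 passed 6. Camera gave adjusted p = 4.48e-06 for osteoblast genes and 1.02e-06 for matrix genes. All 16 genes of the unfolded protein response were negative with a median of −0.38, and 6 fell when adjusted over the list alone (camera adjusted p = 0.000137, and adjusted p = 0.661 with an estimated correlation). Calr, a chaperone gene of the endoplasmic reticulum, had −0.40 and Sel1l, of the degradation machinery there, −0.41. The marrow score was higher in each zinc-deficient library than in each control library, and the osteoblast mean was 6.21, 5.55 and 5.76 log2 CPM in control replicates 4, 5 and 6 and 5.16, 5.27 and 5.17 in the zinc-deficient ones. With that score beside the diet the osteoblast median was −0.98 and the matrix median −0.48. The diet term of the list mean was then −0.99 for osteoblast genes (95% interval −1.81 to −0.16) and −0.61 for matrix genes (−1.96 to 0.74), the latter including 0. These intervals are not adjusted for the 63 lists. The score spanned 1.06 to 3.38 in the control libraries and only 3.79 to 3.96 in the zinc-deficient ones. Its fitted slope therefore rests mainly on the 3 control libraries and is carried beyond their range, so the terms beside it are uncertain. Besides osteoblast genes, only olfactory neuronal progenitor (0.12 to 0.49) and inflammatory genes (−1.30 to −0.18) had intervals without 0. With the score the median of the unfolded protein response was −0.14, and that list no longer passed camera with its preset correlation (adjusted p = 0.181), while chondrocyte genes passed with a median of 0.83 (adjusted p = 5.98e-06).

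Olfactory neuron genes were slightly higher as lists in camera with its preset correlation, with adjusted p = 0.597 with an estimated correlation for mature and immature neurons. Of 20 genes of mature olfactory neurons 19 were positive with a median of 0.28, and edgeR passed none over all genes or when adjusted over the list alone, with 8 at an unadjusted p under 0.05 and 1 past DESeq2. Omp, the marker protein gene of mature olfactory neurons, was at 2706 ± 296 CPM under the control diet and 3903 ± 994 under the zinc-deficient diet (SD, n = 3), a log2 fold change of 0.53 with a standard error of 0.21 (edgeR adjusted p = 0.327), and Adcy3, the adenylyl cyclase of odour signalling, had 0.34. Of 16 genes of immature neurons 15 were positive with a median of 0.32, and 5 rose when adjusted over the list alone. Tubb3, a neuronal tubulin gene, had a log2 fold change of 0.61 (edgeR adjusted p = 0.0849), and Gap43, a growth cone protein gene, had 0.31 (edgeR adjusted p = 0.432). The abundant members Ncam1 and Ebf2 had 0.32 and 0.22. Camera gave adjusted p = 2.7e-05 for mature and 1.94e-05 for immature neurons. The neuronal progenitor list had a median of 0.32 over 12 members and did not pass (camera adjusted p = 0.111). Of its members 2 rose and 1 fell when adjusted over the list alone, and the abundant members Sox11 and Insm1 had 0.42 and 0.63. Horizontal basal cell genes, from the reserve stem cells of the epithelium, had a median of −0.31 over 12 members (camera adjusted p = 0.0313, and adjusted p = 0.661 with an estimated correlation), with the keratin gene Krt5 at 0.08 and the integrin genes Itgb4 and Itga6 at −0.36 and −0.40. Genes of respiratory ciliated cells had a median of −0.33 over 20 members, and 2 fell when adjusted over the list alone (camera adjusted p = 0.000414, and adjusted p = 0.661 with an estimated correlation). Foxj1, their ciliogenesis factor gene, had −0.05, and the axonemal dynein genes Dnah5 and Dnah9 had −0.79 and −0.55. Sustentacular cell genes had a median of 0.04 over 17 members, with the cytochrome genes Cyp2g1 at 0.17, Cyp2a5 at 0.15 and Cyp2f2 at 0.04, and gland genes −0.32 over 19, with the water channel gene Aqp5 at 0.07, Dmbt1 at −1.57 and the mucin gene Muc5b at −0.08. Neither of these lists passed (camera adjusted p = 0.573 and 0.201). The marrow score was higher in each zinc-deficient library than in each control library. With that score beside the diet, horizontal basal and ciliated cell genes no longer passed camera (adjusted p = 0.32 and 0.289), while mature and immature neuron genes passed with the preset correlation (adjusted p = 0.01 and 0.0269).

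Zinc handling genes did not pass edgeR over all genes, with 2 of 3 metallothionein genes, 1 of 8 exporter genes and 3 of 13 importer genes at an unadjusted p under 0.05. DESeq2 passed 1 of the metallothionein genes and 0 of the others. Mt1, which encodes a zinc-binding metallothionein, was at 140 ± 23.4 CPM under the control diet and 86.0 ± 13.3 under the zinc-deficient diet (SD, n = 3), a log2 fold change of −0.71 with a standard error of 0.16 (edgeR adjusted p = 0.133). Mt2 was at 54.3 ± 9.82 and 38.7 ± 0.719 CPM, a log2 fold change of −0.49 with a standard error of 0.15 (edgeR adjusted p = 0.242). The ranges of both genes were separate. The metallothionein list had 3 tested members, too few for the list test, and 2 fell when adjusted over the list alone. The exporter gene Slc30a1 had −0.28, and the importer genes Slc39a4 and Slc39a10 had −0.71 and −0.15. The most abundant exporters, Slc30a9 and Slc30a5, had −0.05 and −0.08, and the most abundant importers, Slc39a9 and Slc39a7, −0.29 and −0.19. The exporter list had a median of −0.08 over 8 genes and the importer list −0.10 over 13, and neither passed (camera adjusted p = 0.255 and 0.42).

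Over all 63 lists tested, 23 passed camera with its preset correlation, 13 higher and 10 lower. With a correlation estimated per list 0 passed, 4 having an unadjusted p under 0.05, and with fry 0 passed, 14 having an unadjusted p under 0.05. Replication-dependent histones and S phase genes were among the 4 (unadjusted p = 0.0203 and 0.045 in camera). The mean, the median or the direction of the test differed in sign for the vomeronasal, metalloproteinase, retinoic acid, oxidative stress and keratinization lists, none of which passed. The other called lists were oxidative phosphorylation, with a median of 0.18 (Atp5b 0.03, Atp5a1 0.17), cholesterol synthesis with −0.26 (Insig1 0.42, Srebf2 −0.18), inflammatory genes with −0.52 (Il33 −0.14, Nfkbia −0.0021) and trace amine receptors with 0.79. Their adjusted p was between 0.597 and 0.671 with an estimated correlation. With the marrow score, which differed between the diets, the median was −0.12 for cholesterol synthesis and 0.51 for trace amine receptors, and neither passed camera (adjusted p = 0.451 and 0.11).

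**Figure D4:**
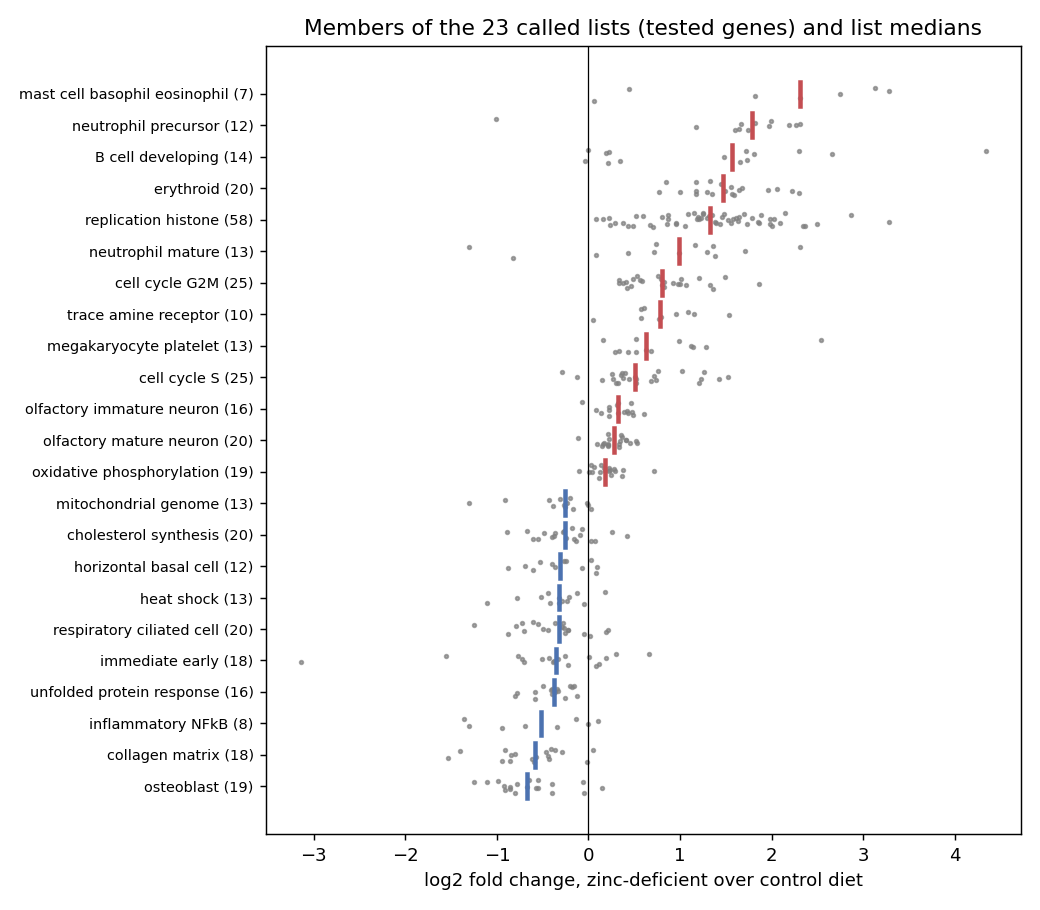
Log2 fold changes, zinc-deficient over control diet, of the tested members (grey points) of the 23 lists that passed camera with its preset correlation, with coloured lines at the list medians and the number of tested members in brackets. Medians run from 2.31 for mast cell, basophil and eosinophil genes to −0.68 for osteoblast genes.

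The counts of the 1113 odorant receptor genes were summed and scaled by the column total, without TMM. This summed CPM was 1635 ± 379 under the control diet and 1813 ± 480 under the zinc-deficient diet (SD, n = 3). The difference of 179 CPM was smaller than the spread between libraries (two-sided exact permutation p = 0.8, smallest possible 0.1), and without zinc-deficient replicate 5 it was −21.5 CPM. Of 648 receptor genes tested one by one, 390 had a positive log2 fold change, and 0 passed edgeR over all genes or when adjusted over the list alone, with 32 at an unadjusted p under 0.05 and 1 past DESeq2. The most abundant, Olfr523 and Olfr522, had 0.22 and 0.43.

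The authors' deposited table gave a list of genes, 65 higher and 41 lower, each at least 2-fold changed with an adjusted p of at most 0.00998 in the authors' own test, which is not described in the sources used here. Of these, 102 were tested here and 17 were among the 22 genes past edgeR, all in the same direction. The CPM ranges of the diets were separate for 90 of the 102 and overlapped for 12, and 75 of them passed DESeq2. The authors' deposited table also gave 330 genes at a fold of at least 1.5, of which 320 were tested and 20 were among the 22. These lists were chosen on the same libraries, so the overlap is not independent evidence.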

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

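The likelihood ratio test, the marrow score and leaving out the 10 most abundant genes were tests chosen after the result was seen. All 22 called genes kept the sign of their log2 fold change under each alternative in which they were tested. Counts of genes changed, higher and lower (22, 16 and 6) moved to 153, 83 and 70 with the replicate number as a block, 172, 104 and 68 with no low-count filter, 349, 203 and 146 with DESeq2, and 265, 156 and 109 with the likelihood ratio test. They moved to 6, 3 and 3 with limma-voom, 14, 14 and 0 on log2(RPKM + 1) with 2252 genes at an unadjusted p under 0.05, 2, 1 and 1 with the marrow score, and 2, 1 and 1 at an adjusted p of 0.01, a stricter limit. Leaving out 1 library gave between 9 and 50 changed, 1 and 45 higher and 2 and 8 lower, and between 21 and 29 lists. Other scalings, the stricter filter, a 2-fold limit and leaving out marrow or abundant genes gave between 18 and 22 changed. Of the 15 genes named by size of change, 6 passed limma-voom, 8 the log2(RPKM + 1) fit and 1 the marrow score, and between 4 and 13 passed with a library left out. Of the 23 lists, 0 passed with an estimated correlation or with fry, and with the marrow score 11 lists passed, 9 of them among the 23. Over all genes chosen by the rule or after seeing the data, printed or not, 3475 of 3669 values kept direction and side of the threshold, 110 gained a call and 84 lost one, and over lists 946 of 1053 kept both, 26 gained, 75 lost and 6 reversed. With the marrow score the median was 0.83 for chondrocyte genes (camera adjusted p = 5.98e-06), against −0.007 without it, −0.38 for mature neutrophils, −0.073 for neutrophil precursors, 0.072 for erythroid genes, for which the direction of the test reversed, and −0.40 for megakaryocytes and platelets. The neutrophil precursor and erythroid lists are part of the score, so that their change follows from its construction. The mature neutrophil list and the megakaryocyte and platelet list are not among the lists of the score, and the cause of their change was not tested. The mitochondrial genome median lay between −0.50 and 0.055 with a library left out, the latter without zinc-deficient replicate 4, and the odorant receptor difference was −21.5 CPM without zinc-deficient replicate 5, in a range of −21.5 to 445. For the other changes the cause was not tested. The correlations gave no clear sign that the replicate numbers pair the samples. Libraries of the same number had correlations of −0.048, 0.151 and 0.068, and of the control libraries only replicate 5 correlated best with its own number. With 3 libraries per diet, centred within each diet, these values cannot exclude pairing. All 22 genes stayed among the 153 called with the block. With 3 libraries per diet and these depths, changes of 1.5-fold were seldom recovered in simulated counts (5 of 50). The alternatives on a pseudocount of 0.1 and on no filter of low values applied to files without counts and were not run.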

Other observations

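The tests on the lower genes, the histones and the mitochondrial ribosomal RNAs were chosen after the result was seen, and the limits for the histones beside the marrow score and for Rn18s-rs5 were redrawn after their values were known. The splits of the libraries and the test of marrow over the called genes were set before, with a score added after seeing the data. Of the 10 trace amine receptor genes tested, a small family of olfactory receptors for amines, all had a positive log2 fold change, with a median of 0.79. One rose when adjusted over the list alone, and none over all genes. Taar9 was at 1.42 ± 0.299 CPM under the control diet and 4.13 ± 1.41 under the zinc-deficient diet (SD, n = 3; edgeR adjusted p = 0.18), and Taar7f had a log2 fold change of 0.78. The list passed camera (adjusted p = 0.000936), had adjusted p = 0.597 with an estimated correlation, and with the marrow score had a median of 0.51 and did not pass (camera adjusted p = 0.11). Of 18 circadian clock genes, 4 fell when adjusted over the list alone and 0 over all genes, and the list did not pass camera (adjusted p = 0.271). Npas2, a partner of the clock protein Bmal1, was at 29.3 ± 2.01 and 16.7 ± 0.332 CPM (edgeR adjusted p = 0.0829), and Nr1d1, a repressor in the clock, was at 77.3 ± 12.6 and 44.8 ± 4.80 CPM (edgeR adjusted p = 0.0849). The more abundant Tef and Per1 had log2 fold changes of −0.07 and 0.18. DESeq2 passed 2 of the clock genes and 1 of the receptor genes.

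Obp1a, Mup4 and Lcn11, genes of secreted odorant- or pheromone-binding proteins, were picked for their wide range between libraries. Obp1a was at 2897, 384 and 2623 CPM in the control libraries and 262, 0.809 and 1392 in the zinc-deficient libraries, in the order of replicates 4, 5 and 6. Mup4 was at 3284, 511 and 2531 CPM and at 282, 1.5 and 1387 CPM. Lcn11 was at 1745, 246 and 1902 CPM and at 456, 8.26 and 985 CPM. None of the 3 passed edgeR (adjusted p = 0.78, 0.761 and 0.783), and each was lowest in zinc-deficient replicate 5. The Y-linked genes Ddx3y and Uty had counts in all 6 libraries, with means of 32.7 and 32.4 CPM under the control diet and 25.4 and 20.7 under the zinc-deficient diet, and Xist was at 1.52 and 1.40 CPM.

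Splitting the 6 libraries 3 against 3 in all 10 ways gave 22 changed, 16 higher and 6 lower genes for the diets with edgeR, each count reached by 1 split, and 0 genes for the other splits, which had between 160 and 1330 genes at an unadjusted p under 0.05. For lists the diets gave 23, a count reached by 3 of the 10 splits, with 30 as the highest of the others. With 10 splits the share cannot go below 0.1, too few for a share under 0.05. Splits that mix the diets called up to 25 and 30 lists. A structure of the samples apart from the diet or a preset correlation that is too low could each give this, and they were not told apart. The list calls with a preset correlation are therefore weak evidence on their own.

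The first pattern is that marrow markers differed between the diets together with the called genes. A different share of marrow in the dissected bone may account for part of it. The erythroid, neutrophil precursor and developing B cell medians were 1.47, 1.78 and 1.57. With the marrow score 21 of the 22 genes lost the call, among them Igll1, which belongs to a list of the score. Over all 22, higher and lower, the genes kept a median of 0.903 of their log2 fold change. Their standard errors grew by a median factor of 1.66, so the calls ended mainly because the score and the diet overlap. Some higher genes kept less, as H2ac11 (2.01 to 1.20) and H2bc7 (2.87 to 1.94), and others kept all, as H2ac10 (2.35 to 2.60) and Ces1a (0.98 to 0.99). For the higher genes as a group, marrow and diet cannot be told apart. For the 6 lower genes the same fit argues against marrow as the whole cause, since they kept between 0.799 and 1.20 of their change (median 1.035). Of them only Nr4a3 still passed. The fit has 3 residual degrees of freedom, and its slope on the score rests mainly on the 3 control libraries. Ces1a and H2ac10 kept as much, so for the lower genes other than Nr4a3 this is weak evidence. A response to the diet stays open and was not tested.

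The next pattern is the rise of the histone genes. Other short classes without a poly(A) tail argue against better recovery of all such RNA. They were the snRNA, snoRNA, scaRNA, miscellaneous RNA and ribozyme classes, without the mitochondrial tRNAs. Their 57 genes had a median log2 fold change of 0.05 (SD 0.77), against 1.33 for histones. Class medians ran from −0.15 for the 27 snoRNA genes to 0.22 for the 13 miscellaneous RNA genes. The 2 tested mitochondrial tRNA genes had a median of 1.74 (SD 2.02). Single small RNAs went both ways, with Rnu2-10 at 1.15 (separate ranges, edgeR adjusted p = 0.191) and Gm23262 at −1.71, so better recovery of some of them is not excluded. Reads moved between copies are argued against by the summed CPM, whose log2 ratio was 0.98 with separate ranges. A larger share of dividing marrow cells remains a candidate explanation. With the marrow score the diet term of the histone mean fell from 1.42 to 0.91, with a standard error of 0.29 and a 95% interval from −0.01 to 1.82 on 3 residual degrees of freedom, so marrow and diet cannot be told apart. An effect of the diet itself was not tested apart from this.

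The last pattern is the fall of the mitochondrial ribosomal RNAs. An equal fall of mitochondrial transcripts of every kind is argued against by the 13 mRNA genes, with a median of −0.25 (SD 0.38) against a mean of −1.31 for both ribosomal RNAs. Only 1 of the 13 was positive, and mt-Nd3 (−1.31) and mt-Atp8 (−0.91) had separate ranges and lay beyond mt-Rnr1 (−0.84). A smaller fall of the mRNA genes is therefore not excluded. The 2 tested mitochondrial tRNA genes had a median log2 fold change of 1.74 (SD 2.02). Stronger depletion of ribosomal RNA in the zinc-deficient libraries could lower the mitochondrial ribosomal RNAs without a change in the tissue. The nuclear 18S gene Rn18s-rs5 had a log2 fold change of 0.34 with overlapping ranges, but each ribosomal RNA has its own depletion probes, so this explanation and an effect of the diet cannot be told apart.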
